A study of Homo sapiens with 99 samples.

How the data were processed

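The series measured how cloned human 3′UTRs change the output of a GFP reporter in HEK293T cells, a human embryonic kidney line. Each reporter sits in a genomic landing pad and carries short barcodes in its transcript, and amplicon sequencing of the barcodes counted each reporter in genomic DNA or RNA. The landing-pad lines were Tet-On (the pilot library, doxycycline switches transcription on), PGK and CAG (constitutive promoters, the full library) and Tet-Off (doxycycline switches transcription off). The 99 libraries comprise 30 from the pilot, 25 from PGK, 26 from CAG and 18 from Tet-Off. Per the labels, RNA was extracted with Trizol, polysomes were separated on a sucrose gradient after cycloheximide, cDNA was made with a reporter-specific primer, and barcodes were amplified by PCR. The software that assigned reads to barcodes is not given in the sources used here.

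The deposited table gives, for each barcode and library, counts per 1e6 reads (CPM) as computed by the authors. The low values of each column were whole multiples of 1 step, and dividing by that step gave whole reads in all 99 libraries, to within 0.001 reads (largest deviation 7.51e-07). Recovered library totals ran from 833625 to 18763052 reads. The barcodes of the table held 91.7% to 96.2% of these totals. The PCR reads carry no molecular identifier that was used here, so read numbers overstate the number of molecules, and counting error is only part of the error.

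The table holds 4245 barcodes of 1404 reporters, with a median of 3 barcodes per reporter. Each reporter is named by the gene whose 3′UTR was cloned, as the file gives the symbol, and 16 genes have 2 reporters, which are told apart by plate and well. Of the 1404 symbols, 1282 matched a current gene symbol of the reference table directly, 104 through 1 synonym, 8 had more than 1 match and 10 had none; current symbols served only to assign genes to lists. The pilot and Tet-Off pools hold the same 174 reporters, and the PGK and CAG pools hold all 1404.

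CPM were summed over the barcodes of a reporter, rescaled with TMM factors and taken to log2 with a pseudocount of 1. Reporters with a mean of at least 5 CPM in the libraries of a comparison were fitted with limma (empirical Bayes with trend and robust settings), and p-values were adjusted by Benjamini-Hochberg over all reporters of the comparison. The threshold was an adjusted p of 0.05, and reporters past it are called higher or lower. The design fixed before the data were examined named edgeR quasi-likelihood on read counts with filterByExpr; because the deposited unit is CPM, limma on log2 values with a CPM filter took its place, and edgeR on the recovered reads was kept as an alternative. All effects are relative within a library: a reporter is higher or lower against the TMM scaling of all reporters, so no absolute amount is given.

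Protein output is the change of a reporter's DNA share from the dimmest to the brightest GFP sort bin: bin 90-100 minus bin 0-10 with bins as groups in the pilot (10 libraries, 2 per bin), and a line over the bin midpoints for PGK and CAG together (10 libraries, 1 per bin and promoter), shown as the change over 90 percentile points. Steady-state RNA is the share in total RNA minus the share in total DNA (pilot 3 and 2 libraries, PGK and CAG 1 of each per promoter, Tet-Off 2 and 2). The polysome slope is the change of the RNA share along the fraction number, shown over 14 fraction numbers (pilot 10 libraries from 2 gradients with different fractions, PGK and CAG 15 fractions each). The labels do not state which end of the gradient fraction 1 is. The decay slope is the change of the RNA share over 0, 1, 2, 3, 4 and 8 h of doxycycline in Tet-Off (12 libraries, 2 batches), shown over 8 h. For the 2 promoters, the difference in protein output and in polysome slope was the interaction, CAG minus PGK.

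The labels number the replicates but do not say whether they were separate cultures, and each promoter is 1 cell population. P-values therefore measure the spread between these libraries. For the lines over bins, fractions and hours, that spread is the scatter of libraries around a straight line. Fractions of 1 gradient and bins of 1 sort are not repeats of each other, so calls from these lines do not cover a repeat of the gradient or the sort. The promoter RNA fit has 1 residual degree of freedom and the Tet-Off RNA fit has 2, so their p-values rest almost wholly on the spread pooled over reporters. Pilot RNA replicates 1 and 2 were nearly identical (chi-square per degree of freedom 1.93, against 24.1 and 26.3 for the other pilot RNA pairs), and their labels share a day that differs from that of replicate 3. They may be 1 RNA sample sequenced again; they were kept as separate libraries (n = 3), and an alternative averaged them.

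Named reporters follow a rule fixed before the data were examined: up to 10 highest and 10 lowest called reporters per comparison with a mean of at least 50 reads and the same sign in each replicate or promoter, up to 4 members with the largest effect per gene list, and a fixed set of genes, of which MYC, FOS, JUN, CDKN1A and HMGA2 were in the library. The same rule was applied to the 0 to 4 h change in Tet-Off. Some reporters that the rule names were withheld; they are left out and were not replaced by the next in rank, but counts and list tests include them. Gene lists, 13 in all, were also fixed: AU-rich immediate-early and cytokine genes, housekeeping and metabolic enzymes, ribosomal proteins and translation factors, transcription factors, chromatin regulators, cell cycle, signalling kinases and RAS pathway, apoptosis, RNA-binding and RNA decay proteins, ubiquitin pathway, plasma membrane and secreted proteins, miR-17/20 family target genes and let-7 target genes. Lists with at least 5 reporters were tested with camera (preset correlation 0.01, and an estimated correlation as an alternative) and with fry, adjusted over the lists of a comparison. List members were fixed by gene name or name prefix. The transcription factor list thus leaves out some such factors of the library, LMX1A and MYB among them. Lists of zinc-finger and HOX genes were added after the data were seen.

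Relations between measures are Pearson and Spearman correlations across reporters with 95% intervals from 1000 bootstrap draws; reporters are not independent replicates, and 16 relations were computed. Agreement between PGK and CAG was measured the same way on values of each promoter alone.

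Alternatives set before the data were examined were other scaling factors (median-of-ratios, library totals alone), no filter, a mean of at least 50 reads, DESeq2 on recovered reads, a replicate block, each replicate left out, each promoter alone, other codings of bins, fractions and time, and the median over the barcodes of a reporter. EdgeR on recovered reads, the test the design had named, became an alternative afterwards. Alternatives added afterwards were pseudocounts of 0.1 and 10, a test over the spread between barcodes in place of libraries, pilot RNA replicates 1 and 2 averaged, 4 h minus 0 h, the 0 to 4 h change and fractions 3 to 15 in the relations, fractions 3 to 15 in the promoter concordance and the gene lists, and the promoter difference without fractions 1 and 2. Isoform pairs and 3′UTR sequence features were not run, because the table names no isoforms and gives no 3′UTR sequence.

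Each fit was tested on simulated data. The simulations changed 50 of 173 or 174 reporters, or 200 of 1404, up and down, exactly along the tested contrast or line. Their libraries were drawn independently. The recovery rates therefore do not cover data in which most reporters change or the change leaves the line. With a 2-fold change, 17 of 17 changed reporters were recovered for pilot protein output, 14 of 17 for the pilot polysome slope, 56 of 67 for promoter RNA, 45 of 67 for the promoter polysome slope and 10 of 17 for the decay slope. The promoter protein fit recovered 3 of 50 reporters changed 2-fold, 16 of 50 changed 4-fold and 50 of 50 changed 16-fold. Its promoter difference recovered 0 of 50 changed 2-fold, 1 of 50 changed 4-fold, 4 of 50 changed 16-fold and 25 of 50 changed 64-fold; the folds of 16 and 64 were added after few were recovered at 2 and 4. The promoter difference in polysome slope recovered 17 of 67 reporters changed 2-fold. Tools were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.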

Results

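The study asked how much single 3′UTRs change protein output, and through which of RNA level, ribosome association and RNA stability. Reporter DNA was counted in GFP sort bins (0-10, 20-30, 40-60, 70-80 and 90-100, in percentiles of GFP), with 2 libraries per bin in the Tet-On pilot and 1 per bin for each of the PGK and CAG promoters. Controls were a bin of all cells (0-100) in the pilot and CAG lines and unsorted cells in the pilot, PGK and CAG lines. Reporter RNA was counted against DNA, in gradient fractions, and after transcription was switched off in the Tet-Off line. Library totals ran from 833625 to 4774740 reads in the pilot, from 6454273 to 14704156 in PGK, from 6406579 to 18763052 in CAG and from 1663205 to 16871053 in Tet-Off. Gene names below stand for the 3′UTR cloned from that gene, since each reporter encodes GFP. Values are log2 differences between shares ± SE unless stated otherwise, and correlations are across reporters, which are not independent replicates.

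In the pilot, protein output, as the log2 ratio of shares in the outer GFP bins, ran from −7.82 to 5.95, with an SD of 3.75 across 173 reporters. The bins are percentiles of GFP, so these values are enrichments between bins and not fold changes in the amount of protein. The 3′UTRs of CAMTA1 (plate 15, well G08; 5.95 ± 0.12), SF3B4 (5.79 ± 0.11), a splicing factor subunit, MORF4L2 (5.70 ± 0.12) and PRR6 (5.66 ± 0.11) were the most enriched in the brightest bin. They were followed by those of CSTF2T, a polyadenylation factor, VGLL1, ACTN2, TAF7, ROR1 and ZSCAN4, from 5.51 to 4.78. At the other end, the 3′UTRs of PKD2, which encodes the channel polycystin-2 (−7.82 ± 0.18), PPIE (−7.72 ± 0.15), SNF1LK (−7.65 ± 0.13), PTF1A, a pancreatic transcription factor (−7.61 ± 0.11), and BCL6B (−7.60 ± 0.11) were the most depleted from it. EZH1, PRDM2, EYA1, RNF4 and LRRK1 followed, from −7.46 to −7.11. Adjusted p for these 20 reporters was at most 2.1e-17 (limma, n = 2 libraries per bin), and the naming rule required the same sign in both sorts.

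In total 166 of 173 pilot reporters differed between the outer bins, 85 higher and 81 lower, and 139 of them by at least 2-fold in share. The split was 99 higher and 67 lower with library totals as the only scaling. Of 12 chromatin regulators, 4 were higher and 7 lower (median −2.07). Of 39 reporters on the transcription factor list, which does not hold all such factors, 18 were higher and 20 lower. Of 6 cell cycle genes, 3 were higher and 3 lower, and of 5 RNA-binding proteins, 3 were higher and 2 lower. The furthest from 0 in these lists, beside those above, were the transcription factors ZNF341 (−6.98), E2F8 (−5.18), ZNF526 (−5.14) and ZNF175 (−5.07), the chromatin regulators CHD1L (4.56), JMJD2A (−4.11) and HTATIP (−3.77), the cyclin-dependent kinases CDK10 (−4.06) and CDK2 (3.21), and the RNA-binding proteins HNRPA1 (−7.06), RBM38 (plate 14, well B10; −4.69), HNRPK (4.10) and RBM15 (1.83). The glycolytic enzyme ENO1 (3.17) and the initiation factor EIF4B (2.58) were higher, EPHB1 was lower (−0.54, and 0.19 with library totals as the only scaling), and GSK3A was not called (0.17). None of these 4 lists differed from the other reporters (lowest camera adjusted p 0.953). With a block for the replicate number, 166 reporters were again called. Cells sorted without regard to GFP showed little of this spread: the 0-100 bin differed from unsorted cells with an SD of 0.28 and 0.12 in the 2 pilot sorts, and 2 and 0 of 173 reporters were beyond 2-fold. Both sorts were set against the 1 unsorted pilot library, that of replicate 1.

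Under the constitutive promoters, the full library again held 3′UTRs of strongly different output. The highest called were those of CRY1, a repressor of the circadian clock (4.56 ± 0.98), ACTN2 (4.36 ± 0.97), ATF2 (4.31 ± 1.16), CRABP1 (4.30 ± 1.17) and HOXC10 (4.28 ± 0.84), then HDGF, HNRPF, CUX1, SNX6 and HDAC5, from 4.22 to 4.17. The lowest were those of HOXD3 (−5.60 ± 0.70), ID3, an inhibitor of DNA binding by bHLH factors (−5.50 ± 0.90), PTF1A (−5.49 ± 1.56), SPEG (plate 11, well F06; −5.46 ± 1.11) and RNF4, a ubiquitin ligase (−5.35 ± 1.09), then CDKN1C, TRAF2, PLK4, FST and NFKBIA, from −5.29 to −5.11. Their adjusted p (limma) ran from 0.000341 to 0.0105, and the naming rule required the same sign in both promoters. The other SPEG reporter stood at −0.47, far from the named one. Of 1404 reporters 786 followed the bins, 355 higher and 431 lower, all by at least 2-fold in share over 90 percentile points. That floor reflects the power of the fit, which recovered 3 of 50 simulated 2-fold changes, so smaller changes could hardly be called. Each promoter alone, with 5 libraries, gave 350 calls (PGK) and 392 (CAG). With library totals as the only scaling the balance turned to 421 higher and 351 lower.

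The AU-rich immediate-early and cytokine genes, whose mRNAs are known for short lives, formed the list with the clearest shift in protein output. They were listed by gene, and the AU content of the cloned 3′UTRs was not measured. The pilot and Tet-Off pools did not hold this list, so its RNA decay was not measured either. Of 17 such 3′UTRs, 14 were lower, none was higher and 3 were not called, and 15 were lower when adjusted over the list alone (median −3.43). Among them were NFKBIA, the inhibitor of NF-κB (−5.11 ± 1.07), KLF2 (−4.45 ± 1.29), KLF10 (−4.21 ± 0.86), PIM1 (−4.07 ± 1.28), JUN (−3.75 ± 0.69), FOS (−3.43 ± 1.28), MYC (−2.84 ± 0.79) and the cell cycle inhibitor CDKN1A (−2.53 ± 0.94). The list differed from the other reporters with a camera adjusted p of 0.000449, and with adjusted p = 0.793 with an estimated correlation.

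**Figure D1:**
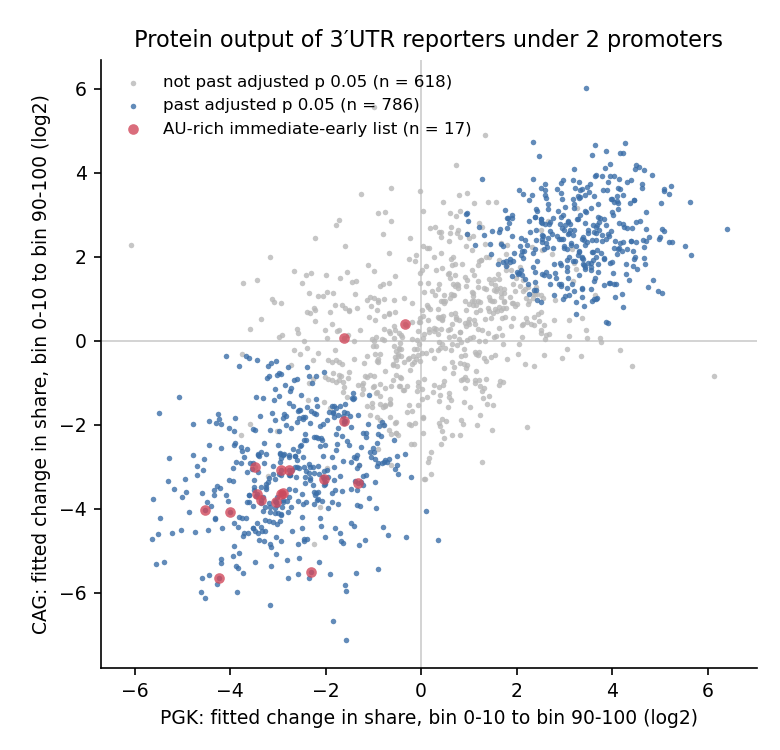
Protein output of 1404 3′UTR reporters under PGK (x axis) and CAG (y axis), each as the fitted log2 change in DNA share from bin 0-10 to bin 90-100 (5 libraries per promoter). Grey points were not past adjusted p 0.05, blue points were (786), and red points are the 17 3′UTRs of the AU-rich immediate-early gene list, of which 14 were called lower.

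All 3 miR-17/20 family targets were lower, PKD2 (−5.01 ± 1.40), E2F1 (−3.60 ± 0.96) and CDKN1A, a list too small to test. Of 9 let-7 targets 6 were lower, such as HRAS (−4.49 ± 0.71), CDC25A (−4.03 ± 0.82), MYCN (−3.47 ± 1.31) and ARID3B (−3.35 ± 0.73), and 2 were higher, HMGA2 (1.69 ± 0.65) among them. Cell cycle genes had 15 lower and 8 higher of 34, with CDKN1C, PLK4, CENPA (−4.25 ± 0.76) and CENPQ (−4.19 ± 0.97) the furthest from 0. Chromatin regulators had 23 lower and 14 higher of 60, with HMGXB3, CBX8, ARID5A and BRD8 between −5.09 and −4.23. Signalling kinases had 10 lower and 8 higher of 31, with MAP3K5 at −4.94 ± 1.33, MAP2K3 at −4.33 ± 0.74 and MAP3K8 at −3.88 ± 1.30. RNA-binding proteins had 13 higher and 9 lower of 40, with HNRPF high (4.19 ± 0.95) and RBM38 (plate 14, well B10; −4.86 ± 0.79), CNOT4 (−3.87 ± 1.04) and ZFP36, which binds AU-rich elements (−3.71 ± 0.91), low. The other RBM38 reporter stood at 0.16, so the low value holds for 1 of the 2 RBM38 reporters.

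Transcription factors had 92 lower and 82 higher of 333, the 3′UTRs of HOXC8 (−5.07 ± 0.68) and REL (−4.66 ± 1.30) among the lowest. Membrane and secreted proteins had 3 lower and 2 higher of 11, with EPHB3 and EPHA10 at −4.21 and −2.58 and SLC26A3 and EPHA6 at 3.55 and 3.08. Ubiquitin pathway genes had 3 higher and 2 lower of 11, with RNF43 at −3.94, RNF113B at 2.92 and TRIM39, not called, at −3.18. Of 11 members of the list of ribosomal proteins and translation factors 4 were lower and 2 higher: the subunits of initiation factor 3 EIF3S9 and EIF3S10 lay at −4.01 and 3.45, while RPS6KA5 and RPS6KA1 (−3.45 and −3.33) encode protein kinases. Apoptosis genes were 2, CASP8AP2 lower (−2.79) and BCL2L1 higher (2.27), and the 1 housekeeping gene, ENO1, was not called (1.20). None of these lists with at least 5 reporters passed camera (adjusted p 0.748 or more).

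Protein output carried over between promoters and lines. PGK and CAG values correlated across 1404 reporters with r = 0.74 (95% interval 0.71 to 0.76, rho 0.73), and 77.2% of reporters lay on the same side of the median in both. All 98 reporters called in both the pilot and the promoter fit had the same direction, 49 higher and 49 lower, with r = 0.91 (0.88 to 0.93) over 173 reporters. A difference between CAG and PGK was called for 0 of 1404 reporters with limma, against 93 at an unadjusted p under 0.05, 32 with DESeq2 and 1 with edgeR. On simulated data this test recovered 25 of 50 reporters that differed 64-fold, 4 of 50 that differed 16-fold and 1 of 50 that differed 4-fold. With 1 library per bin it thus rarely called differences of 4-fold or 16-fold. The labels give separate days for the PGK and the CAG sort, so promoter and sort day cannot be told apart in this difference. In the CAG line the 0-100 bin differed from unsorted cells with an SD of 0.39, and 37 of 1404 reporters were beyond 2-fold.

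Steady-state RNA also differed widely between 3′UTRs. Under PGK and CAG, the 3′UTRs of LMX1A (−4.09 ± 0.32), ING4 (−3.98 ± 0.36), ZNF425 (−3.89 ± 0.34), MYB (−3.27 ± 0.29), ZFP36 (−3.27 ± 0.29), FOS (−3.20 ± 0.23) and FOXA1 (−3.17 ± 0.24) had the lowest RNA share for their DNA share, with GRK5, NRL and TXNIP from −3.13 to −3.05. The highest were PTMS (1.92 ± 0.21), PRKACG (1.63 ± 0.19), FLNA, a filamin (1.62 ± 0.19), CDKL3 (1.62 ± 0.17), BZW2 and ATF2, with CAMTA1 (plate 15, well G08), NEK10, SYCP3 and SF3B4 near 1.51. The other CAMTA1 reporter stood at 0.115. Of the AU-rich list 13 of 17 were lower and none higher (median −1.47, camera adjusted p 1.5e-05, and adjusted p = 0.92 with an estimated correlation), PIM1 (−2.52 ± 0.35), CDKN1A (−1.75 ± 0.29), JUN (−1.71 ± 0.23) and MYC (−1.12 ± 0.20) among them. HMGA2 was higher (0.70 ± 0.18). Of 11 translation-related genes 7 were lower, such as EIF4A2 (−2.14 ± 0.21) and NCL (−1.37 ± 0.18), with a camera adjusted p of 0.0971. Its members RPS6KA5 and EIF3S9 stood at −1.84 and −1.59. None of the other lists passed camera.

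The other lists held low members of several kinds. Chromatin regulators had 19 lower and 14 higher of 60, with ARID3B (−2.52), CHD4 (−2.11), HMGXB3 (−1.71) and EZH1 (−1.61) the furthest from 0. Cell cycle genes had 15 lower and 7 higher of 34, with WEE1 (−2.34), MCM3 (−2.02), E2F1 (−2.01) and CENPA (−1.91). Signalling kinases had 9 lower and 8 higher of 31, with MAP3K8 (−2.71), FRAP1, which encodes mTOR (−1.85), and MAP3K5 (−1.64) lower and PRKACG higher. RNA-binding proteins had 14 higher and 11 lower of 40, with ZFP36, RBM17 (−1.56), ZFP36L2 (−1.53) and HNRPM (1.40). The transcription factor list, which holds ZFP36 through its name and does not hold LMX1A or MYB, had 101 lower and 87 higher of 333, with ZNF425, ZFP36, FOS and FOXA1 its members furthest from 0. Ubiquitin pathway genes had 4 lower and 3 higher of 11, with TRIM39 (−3.00), RNF152 (−2.50), RNF43 (−2.41) and RNF4 (−1.02). Membrane and secreted proteins had 3 higher and 2 lower of 11, with EPHA6 (1.09) and KCNIP3 (1.05), EPHA10 (−1.86), and EPHB1 at −1.15 ± 0.55. All 3 miR-17/20 targets were lower, E2F1, PKD2 (−1.98) and CDKN1A, and of 9 let-7 targets 5 were lower and 3 higher, ARID3B and MYCN (−1.68) against HMGA1 (1.49). CASP8AP2 was lower (−1.24), and BCL2L1 (−0.54) and ENO1 (0.16) were not called.

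In all, 822 of 1404 reporters were called in promoter RNA, 392 higher and 430 lower, and 343 of them by at least 2-fold. With library totals as the only scaling the split was 315 higher and 511 lower. PGK and CAG RNA correlated across reporters with r = 0.83 (0.79 to 0.86). In the pilot, 155 of 174 were called, 76 higher and 79 lower, 41 of them by at least 2-fold. Library totals as the only scaling gave 64 higher and 93 lower there. Replicates 1 and 2 of pilot RNA were nearly identical, and averaged as 1 sample they left 146 of these 155 called. The 3′UTRs of SF3B4 (1.53 ± 0.03), VGLL1, MAZ, CSTF2T, ZMIZ2, ACTN2, MORF4L2, LBX1, ZFP42 and ADCK1 were the highest there. The lowest were SNF1LK (−3.27 ± 0.19), ZNF625 (−2.94 ± 0.09), MAP1LC3B, which encodes the autophagy protein LC3B (−2.25 ± 0.07), and PTF1A (−2.18 ± 0.11), then PPIE, PRDM2, LRRK1, ZNF341, ATF7IP and ZNF581. In the lists, EZH1 (−1.35), HNRPA1 (−1.07), PKD2 (−1.05), RNF4, CDK10 (−0.78), E2F8 (−0.51), CDC2L5 (−0.49), RBM15 (−0.48) and EPHB1 (−0.46) were lower. SIRT2 (1.02), HMG20B (0.98), ENO1 (0.90), GSK3A (0.82), CDK2 (0.79), EIF4B (0.74) and HNRPK (0.52) were higher, RBM41 stood at 0.20 ± 0.08, and no list passed camera. Tested over the spread between barcodes of a reporter, 0 of 148 pilot RNA reporters were called, against 155 over libraries (edgeR 155, DESeq2 161), so these calls hold for these barcodes alone. The values changed little: 39 of the 148 were at least 2-fold there, and they correlated with the values over libraries with r = 0.948.

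In the total RNA libraries of Tet-Off cells, whose labels give no time of doxycycline, 152 of 174 reporters differed in RNA, 73 higher and 79 lower. CAMTA1 (plate 15, well G08; 1.83 ± 0.05), MORF4L2 (1.79 ± 0.05), THAP10 and DMRTA1 were the highest, then SF3B4, POU5F1, CHD1L, TAF7, APEX1 and HIPK3. SNF1LK was by far the lowest (−6.92 ± 0.18; mean 7.24 CPM in RNA against 997 CPM in DNA), and others among the lowest were MTHFSD (−2.52 ± 0.08), PSKH1 (−2.13 ± 0.10), EPHB1, PPIE, SAMD14, IRF8, EZH1 and ZNF581. In the lists, RBM15 (1.32), ZFP42 (1.25), ZNF860 (1.24), HDAC8 (1.09), HNRPK (0.99), CDK2 (0.98), PRR6 (0.61) and GSK3A (0.19) were higher. RNF4 (−1.46), PKD2 (−1.07), RBM38 (plate 14, well B10; −1.04), HNRPA1 (−0.81), CDK10 (−0.33) and CDC42BPG (−0.24) were lower, ENO1 (0.08) and EIF4B (0.07) were not called, and no list passed camera. Of 137 reporters called in both Tet-Off and pilot RNA, 114 had the same direction and 23 the opposite one, and the 2 measures correlated with r = 0.67 (0.56 to 0.77). With library totals as the only scaling the split was 57 higher and 97 lower, and over the spread between barcodes 60 of 148 reporters were called.

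Along the gradient, 12 of the 17 3′UTRs of the AU-rich list lost share toward high fraction numbers. Under PGK and CAG the lowest slopes, over 14 fraction numbers, were those of HES5 (−4.13 ± 0.42), the kinase MAP3K8 (−3.79 ± 0.31), PTF1A (−3.68 ± 0.36), FOS (−3.45 ± 0.23), ZC3H12A, an RNase of inflammatory mRNAs (−3.40 ± 0.28), MKRN3, SNF1LK, ZFP36, SMAD6 and TCF21. These 10 were also called lower without fractions 1 and 2, at −3.51 to −1.46. Of that list 12 were lower, 1 was higher and 4 were not called (median −1.20, camera adjusted p 6.4e-08, adjusted p = 0.00666 with an estimated correlation), with MYCN at −2.46 ± 0.17, NFKBIA at −2.35 ± 0.18 and JUN at −0.70 ± 0.18. Without fractions 1 and 2 there were 13 lower and 1 higher (median −1.36, adjusted p 1.9e-05, adjusted p = 0.369 with an estimated correlation).

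The highest slopes, those of THAP3 (3.09 ± 0.99), MAG, DPF1, RFX2, SAMD4B, DMRTB1, LOC93349, NFKBIE, ZBTB42 and CBX1 (2.35 ± 0.77), rested on fractions 1 and 2. Without these, NFKBIE (−0.70) and RFX2 (−0.36) were called lower, DPF1 alone was still called higher (0.21), and the other 7 were not called. MYC (−0.39 ± 0.27), HMGA2 (−0.46 ± 0.31) and CDKN1A (−0.11 ± 0.76) were not called over all 15 fractions. Over fractions 3 to 15 MYC and HMGA2 were higher (0.40 and 0.61) and CDKN1A lower (−1.74).

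The counts of the other lists over all 15 fractions were as follows. Of chromatin regulators, 14 were higher and 12 lower, SETD4 (2.20 ± 0.43), HDAC8 (1.81 ± 0.45) and SETD8 (1.71 ± 0.34) among the higher ones; of cell cycle genes, 6 were higher and 9 lower, PLK2 (−1.57 ± 0.29), PLK4 (−1.54 ± 0.25) and WEE1 (−1.46 ± 0.26) among the lower ones. CDK2 stood at 1.64 ± 0.69. Of signalling kinases 5 were higher and 6 lower, with MAP3K5 lower (−2.07 ± 0.14) and SRC (1.81 ± 0.64) higher. Of RNA-binding proteins 11 were higher and 9 lower, with PTBP1 (1.42), FXR2 (−1.36) and CNOT4 (−1.22). Of transcription factors 99 were higher and 54 lower, of ubiquitin pathway genes 2 were higher, RNF152 (1.19) and TRIM32 (0.41), and 1 lower, RNF4 (−1.16), with UBE3A (0.62) not called. Of translation-related genes 2 were higher, EIF4B (1.19) being 1, and 3 lower, EIF2AK3, a kinase of initiation factor 2, the lowest (−1.53 ± 0.12), with RPS6KA1 (1.22) and NPM1 (−0.90) not called. Of the 11 members of the list of membrane and secreted proteins, 2 were higher, KCNIP3 (1.26) being 1, and 0 lower. EPHB2 (1.77), WNT3A (0.61) and EPHB1 (0.60) of that list were not called. Of let-7 targets 1 was higher, HMGA1 (0.78), and 3 lower, MYCN and E2F6 (−0.77 ± 0.20) among them, and ARID3B was not called (0.87). PKD2 (−2.37 ± 0.29) and CASP8AP2 (−1.18) were lower and BCL2L1 higher (1.80), while E2F1 (−0.30) and ENO1 (−0.83) were not called.

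Without fractions 1 and 2 the balance of several lists turned. Transcription factors then had 113 higher and 127 lower, chromatin regulators 21 and 25, cell cycle genes 14 and 15, signalling kinases 9 and 13, RNA-binding proteins 15 and 15, ubiquitin pathway genes 4 and 6, translation-related genes 3 and 5, membrane proteins 3 and 4, and let-7 targets 3 and 5. None of these lists passed camera there (adjusted p 0.808 or more). In the same fit, EIF4B (−0.32), RPS6KA1 (−0.48), UBE3A (−0.30), WNT3A (−1.11) and ARID3B (−1.01) were called lower, and ENO1 (0.64) and NPM1 (0.55) higher, each with the opposite sign to the slope over all fractions. SRC (−0.47), EPHB2 (−0.37), HMGA1 (−0.24), CDK2 (−0.12), EPHB1 (−0.12) and PTBP1 (−0.088) also changed sign and were not called. MAP3K5 (−1.58), EIF2AK3 (−1.34), CASP8AP2 (−1.07), PKD2 (−2.62), RNF4 (−1.93), CNOT4 (−2.29), WEE1 (−1.86) and SETD4 (0.56) kept their sign and were called.

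Over all fractions 604 of 1404 slopes were called, 347 higher and 257 lower. The split was 422 higher and 191 lower with library totals as the only scaling. Without fractions 1 and 2, 1048 were called, 520 higher and 528 lower; 398 reporters were called in both, 348 in the same direction and 50 in the opposite one. The majority also turned with the tool, to 241 higher and 414 lower with DESeq2 and 222 and 390 with edgeR. Each promoter alone gave 348 (PGK) and 266 (CAG) calls. The difference between promoters was called for 0 of 1404 reporters with limma, against 109 at an unadjusted p under 0.05, 2 with DESeq2 and 0 with edgeR. Slopes of PGK and CAG correlated with r = 0.79 (0.76 to 0.81), and over fractions 3 to 15 with r = 0.94 (0.93 to 0.95).

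**Figure D2:**
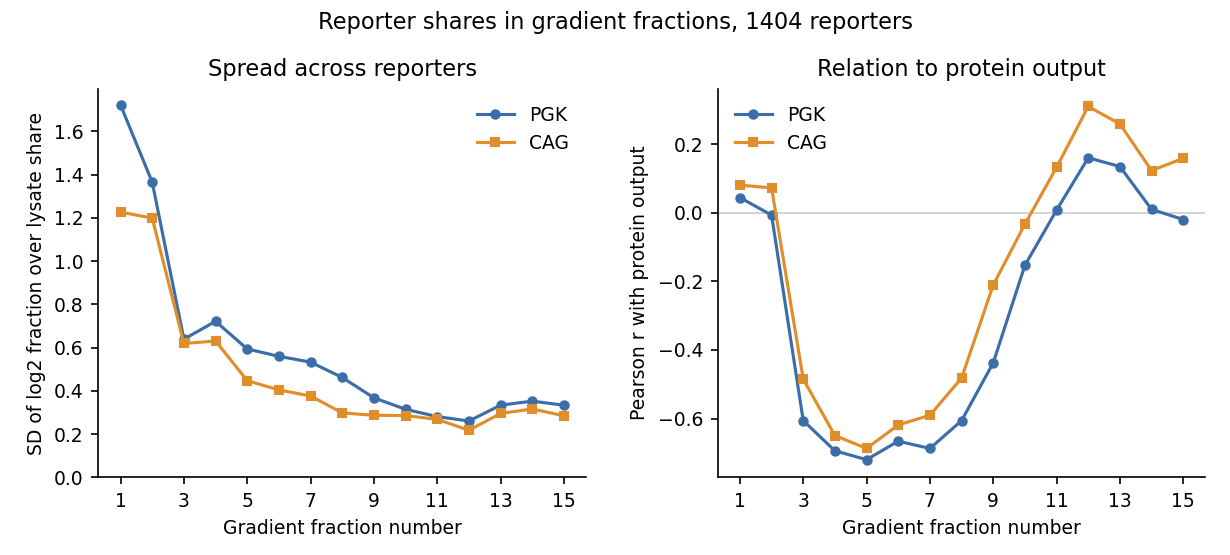
Left, SD across 1404 reporters of the log2 ratio of fraction share to cytoplasmic lysate share by gradient fraction number (1 library per point); right, Pearson r across reporters between that ratio and protein output. Fractions 1 and 2 had SDs of 1.20 to 1.72 against 0.22 to 0.72 in fractions 3 to 15, and r reached −0.72 in fraction 5 of PGK and 0.31 in fraction 12 of CAG.

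In the pilot gradients, with fractions 6 to 20, the slopes of 91 of 174 reporters were called, 43 higher and 48 lower. The highest were PRR6 (1.86 ± 0.29), ZSCAN4 (1.59 ± 0.28), SF3B4 (1.55 ± 0.26) and ZMIZ2 (1.49 ± 0.30), then ZNF589, CHD1L, ZNF226, PSMC2 (plate 14, well H03), POU5F1, a pluripotency factor, and VGLL1. The lowest were SNF1LK (−3.26 ± 0.77), PTF1A (−2.83 ± 0.37), PKD2 (−2.54 ± 0.34) and EYA1 (−2.05 ± 0.23), then BCL6B, RNF4, LRRK1, ZNF175, LHX6 and JMJD2A. The SE does not cover the spread between barcodes. The 2 barcodes of ZMIZ2 had an SD of 1.61, above its slope, against 0.14 for SF3B4. ZNF589, PSMC2, BCL6B and LHX6 rested on 1 barcode each. In the lists, RNF4 (−1.84), ZNF782 (−1.28), E2F8 (−1.27), RBM41 (−0.81), HNRPA1 (−0.74) and EPHB1 (−0.51) were lower and ENO1 (0.68) and PHF1 (0.56) higher. EZH1 stood at −1.19 ± 0.54 and CDC42BPG at 0.42 ± 0.19, and EIF4B (−0.29), HNRPK (0.22), RBM38 (plate 14, well B10; −0.22), GSK3A (−0.21) and CDK2 (0.20) were within 1.5 SE of 0. No list passed camera. The replicate block gave 101 calls, gradient 2 alone 78 and gradient 1 alone 31. Pilot slopes correlated with those of PGK and CAG with r = 0.30 over all fractions and 0.86 (0.80 to 0.90) without fractions 1 and 2, where all 74 reporters called in both had the same direction.

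After transcription was switched off, the 3′UTRs of SF3B4, CAMTA1 and other reporters of high protein output gained share of the remaining reporter RNA over the first 4 h. In a fit over 0 to 4 h, an alternative set before the data were examined, SF3B4 rose most (1.97 ± 0.09 over 4 h), then CAMTA1 (plate 15, well G08; 1.89 ± 0.10), VGLL1 (1.81 ± 0.11), CSTF2T (1.79 ± 0.10), MORF4L2, ACTN2, POU5F1, GTF2IRD2B, PRR6 and NCOR1 (plate 14, well A03), to 1.49. Among the called reporters with the lowest fitted line were ESRRB (−1.52 ± 0.33), STRA6, the retinol transporter (−1.45 ± 0.17), and TLE3 (−1.44 ± 0.28). PREB, RBM38 (plate 14, well B10), ZNF341, TNK1, HDAC7A and ISL1 followed, to −1.22. A straight line does not rank reporters by how fast their share fell at the first hours. Of 174 reporters 143 were called, 62 higher and 81 lower. The median over all reporters was −0.28 in this fit, so a reporter called lower is not always below the typical reporter. For 4 h minus 0 h the median was −0.10, with 72 higher and 84 lower. Of 5 RNA-binding proteins 4 were higher and 1 lower, of 12 chromatin regulators 4 were higher and 7 lower, and no list passed camera. In the lists, ZNF619 (1.37), HNRPA1 (1.30), ZNF479 (1.27), ATF7IP (1.23), CHD1L (1.17), RBM41 (1.11), ENO1 (1.07) and HNRPK (0.99) were higher. CBX8 (−1.18), CDK10 (−1.16), RNF4 (−1.08), PKD2 (−1.05), E2F8 (−1.01), CDC42BPG (−0.96), GSK3A (−0.71) and EPHB1 (−0.64) were lower, and EIF4B was not called (0.17).

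**Figure D3:**
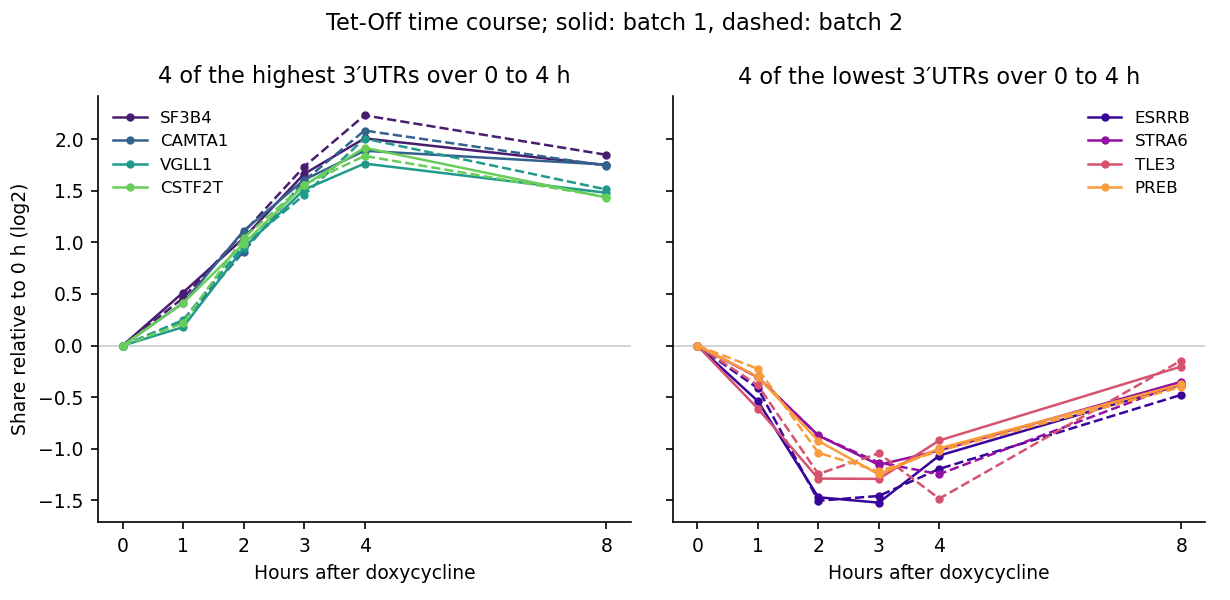
Share of reporter RNA relative to 0 h (y axis, log2) against hours after doxycycline (x axis) in Tet-Off cells. Shown are the 4 3′UTRs with the highest fitted change and 4 of the called ones with the lowest fitted change over 0 to 4 h. Solid lines are batch 1 and dashed lines batch 2. SF3B4 stood at 2.01 and 2.23 at 4 h and at 1.75 and 1.85 at 8 h, and the 4 falling reporters shown had returned to between −0.48 and −0.14 at 8 h.

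The slope over 0 to 8 h, which was the main test, called 0 of 174 reporters with limma, against 22 at an unadjusted p under 0.05, 17 with DESeq2 and 0 with edgeR. The change was not linear: the SD of the log2 change from 0 h was 0.82 and 0.87 at 4 h in the 2 batches, 0.48 in both at 8 h, and 0.24 and 0.27 at 20 h. List members furthest from 0 were HNRPA1 (1.24 ± 0.31), PRR6 (1.11 ± 0.39), ZNF619 (0.91 ± 0.36), ENO1 (0.86 ± 0.29), ZNF479 (0.81), ATF7IP (0.79), CHD1L (0.77), ZNF625 (0.71) and EZH1 (0.67), none of them called. The other members named by the rule lay between −0.47 (GSK3A) and 0.47 (HNRPK). Times taken as groups gave 99 calls for 8 h minus 0 h. A block for the batch number left the count at 0. The values give loss relative to the other reporters and not half-lives.

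Protein output followed RNA, gradient position and the share change over 0 to 4 h of doxycycline in Tet-Off. Across 1404 reporters it correlated with RNA at r = 0.69 (0.66 to 0.72), and with the polysome slope at 0.31 (0.26 to 0.36), or 0.73 (0.71 to 0.75) without fractions 1 and 2. Of 431 3′UTRs with lower protein output, 248 were lower in both RNA and slope over fractions 3 to 15, 29 were lower in RNA with the slope not called, and 95 were lower in slope with RNA not called. The RNA was lower and the slope higher in 7, and the reverse held in 1. Of 355 with higher output, 211 were higher in both, 48 in RNA with the slope not called and 33 in slope with RNA not called. The RNA was higher and the slope lower in 11, and the reverse held in 14. RNA alone accounted for 48.0% of the variance of protein output, the slope over all fractions for 9.64% and the slope over fractions 3 to 15 for 53.1%. RNA and slope together accounted for 49.4% with all fractions and for 62.1% with fractions 3 to 15, a choice made for this relation after the data were seen. In fractions 3 to 8 of both promoters, share relative to lysate also correlated with the ratio of DNA to RNA at r = 0.41 to 0.62, so the slope over fractions 3 to 15 is not independent of RNA level, and genomic DNA in these fractions was not excluded. The 0 to 4 h change, also chosen for this relation after the data were seen, correlated with pilot protein output at r = 0.80 (0.71 to 0.87). The 0 to 8 h slope, the main test, gave 0.31 (0.13 to 0.48). In the pilot, RNA and polysome slope together accounted for 59.8% of the variance. Adding the 0 to 4 h change gave 80.3%, and adding the 0 to 8 h slope gave 63.1%. The share change is relative to other reporters and is not a measured half-life. Of 138 reporters called in both the 0 to 4 h change and pilot protein output, 128 had the same direction.

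**Figure D4:**
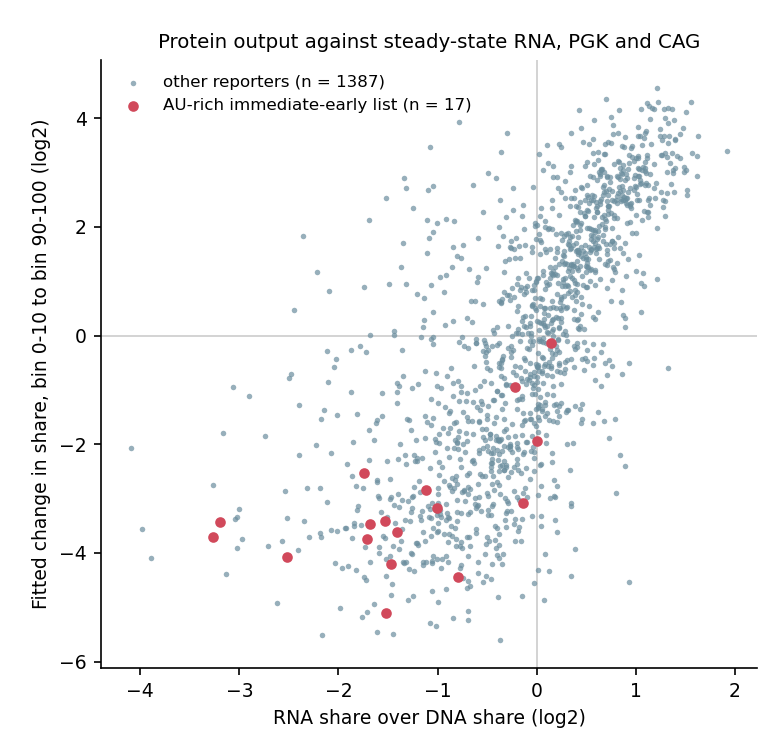
Protein output (y axis, fitted log2 change in DNA share from bin 0-10 to bin 90-100) against steady-state RNA (x axis, log2 RNA share over DNA share) for 1404 reporters, PGK and CAG fitted together. Red points are the 17 3′UTRs of the AU-rich immediate-early gene list, with medians of −3.43 in protein output and −1.47 in RNA.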

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

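The test over the spread between barcodes was chosen after the library-level results had been seen, and the counts of splits over all bins and fractions were set before their results were seen. Tested over the spread between the barcodes of a reporter, 84 reporters differed in protein output between CAG and PGK, 59 higher in CAG and 25 lower, 1 of them with the opposite sign when its barcodes were summed, while limma over libraries called 0 (93 at an unadjusted p under 0.05, DESeq2 32, edgeR 1). The extremes of these 84 were MEFV (5.89), MLKL (5.66), PRDM7 (plate 12, well C04; 5.46) and EGFR (5.29), and RNF6 (−5.92), CBX8 (−4.79), MAPKAPK5 (−4.46) and HNRNPH1 (−4.28), chosen after their values were seen. Barcodes of a reporter share the sorted libraries, so this test holds for these cell populations and not for a repeat of the sort. PGK and CAG were sorted on separate days, per the labels, so a difference between promoters cannot be told apart from one between sort days.

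For protein output, 1 of 16 swaps of promoter labels within bins, the real one, gave as many reporters at an unadjusted p under 0.05 (93, against 78 in the highest other), and 16 splits cannot give a share under 0.05. For the polysome slope, 24 of 100 drawn swaps gave at least the real 109, and the highest other swap gave 513. Without fractions 1 and 2, a count made after these were seen, 25 of 97 such swaps gave at least the real 129. The highest other gave 1021. A swap in some bins or fractions turns a constant share difference between PGK and CAG into a difference in slope. The swapped counts therefore do not measure chance alone, and chance stays open for both measures.

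Reporters outside the 174 of the pilot and Tet-Off pools had traces of reads, 185 reporters in the pilot (highest mean 2.97 CPM) and 150 in Tet-Off (highest mean 2.66 CPM), against medians of 5382 and 4334 CPM for reporters of the pools.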

How the results depend on the processing

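EdgeR, which the design had named as the test, was made an alternative once the deposited unit was seen. Tests over the spread between barcodes, with other pseudocounts, with pilot RNA replicates averaged, at 4 h minus 0 h, and the relations over fractions 3 to 15 or over 0 to 4 h were chosen after the data were seen. Of 63 results that answer a comparison, 30 held under each alternative tried, and of 329 values under alternatives 269 stayed within the spread or within 1.5 times the count while 60 moved. Of 356 results for named reporters, 317 had no reversal; of their 4420 values 3976 kept direction and call, 237 lost the call, 48 gained it, 105 moved and 54 reversed. Isoform pairs and 3′UTR sequence features were not run, and without 1 replicate the pilot protein and Tet-Off RNA fits have values but no test. Library totals as the only scaling moved the median of all reporters from 0.03 to 0.75 in pilot protein output, from −0.14 to 0.19 in promoter protein output, from 0.06 to 0.25 in the promoter polysome slope, from −0.04 to −0.26 in Tet-Off RNA, from −0.03 to −0.19 in pilot RNA, from −0.03 to −0.16 in promoter RNA, from −0.04 to −0.15 in the pilot polysome slope and from 0.002 to −0.27 in the decay slope. Where no cause is given, the cause was not tested.

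The decay slope, with 0 reporters called by limma, had 17 called with library totals (7 at least 2-fold), 7 without a filter (5), 17 with DESeq2 (11), 143 over 0 to 4 h (62), 99 for 8 h minus 0 h (12), 156 for 4 h minus 0 h (38) and 87 over the spread between barcodes (11). The promoter difference in protein output, 0 with limma, had 32 with DESeq2, 1 with edgeR, 1 without the bin 40-60 libraries and 84 between barcodes, all at least 2-fold. The promoter difference in polysome slope, 0 with limma, had 2 with DESeq2 and 1 between barcodes (1 at least 2-fold), and in place of 98 fitted at least 2-fold, called or not, it had 206 with the median over barcodes, 210 between barcodes, 57 with a pseudocount of 10, 40 with DESeq2, 39 with edgeR, 21 for fractions 8 to 15 against 1 to 7 and 2 without fractions 1 and 2. Promoter protein output had 350 calls in PGK alone and 392 in CAG alone, all at least 2-fold, with 5 libraries each in place of 10. The promoter polysome slope had 348 in PGK alone, 266 in CAG alone (151 at least 2-fold), 388 for fractions 8 to 15 against 1 to 7 (40) and 1048 without fractions 1 and 2. Between barcodes, pilot RNA had 0 calls (0 at least 2-fold) and Tet-Off RNA 60. Doxycycline 0 h RNA in place of total RNA gave 28 called at least 2-fold in Tet-Off RNA in place of 47. The pilot polysome slope had 2 called at least 2-fold for the highest fraction against lysate, and 31 to 78 calls, 18 to 50 of them at least 2-fold, with 1 gradient left out.

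Without fractions 1 and 2, r rose to 0.729 between promoter slope and protein output, 0.630 between RNA and slope and 0.859 between pilot and promoter slopes. With the 0 to 4 h change, r was 0.584 with Tet-Off RNA, 0.796 with pilot and 0.829 with promoter protein output. Spearman's rho between promoter RNA and protein output was 0.742, and a prior count of 5 gave 0.835 for the PGK and CAG slopes. With fry, which does not compare a list with other genes, lists past the threshold were 3 in pilot protein output, 3 in pilot RNA, 3 in the pilot slope, 3 in promoter protein output, 5 in the promoter slope, 2 in Tet-Off RNA and 1 in the decay slope. In promoter RNA fry also gave 1, but another list: chromatin regulators (adjusted p 0.0402) and not the AU-rich list (0.0965). With an estimated correlation they were 0 in promoter protein output and 0 in promoter RNA.

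Without fractions 1 and 2 the promoter slope reversed for THAP3 (−0.051), RFX2 (−0.36), DMRTB1 (−0.13), LOC93349 (−0.10), NFKBIE (−0.70), ZBTB42 (−0.067), ARID3B (−1.01), CDK2 (−0.12), EIF4B (−0.32), ENO1 (0.64), EPHB1 (−0.12), EPHB2 (−0.37), HMGA1 (−0.24), HMGA2 (0.61), MYC (0.40), NPM1 (0.55), PTBP1 (−0.088), RPS6KA1 (−0.48), SRC (−0.47), UBE3A (−0.30) and WNT3A (−1.11). It also reversed with DESeq2 for ARID3B (−0.51), EPHB1 (−0.064) and WNT3A (−0.23), and with edgeR for ARID3B (−0.49), EPHB1 (−0.030) and WNT3A (−0.22). CDKN1A reversed in PGK alone (0.74), with a pseudocount of 0.1 (0.45), without fractions 14 and 15 (0.17), and with the median over barcodes and between barcodes (0.12 each), and E2F1 in the last pair (0.52 and 0.12). Over 0 to 8 h in place of 0 to 4 h, reversals were CDK10 (0.18), EIF4B (−0.040), EPHB1 (0.053), PKD2 (0.22), RNF4 (0.13), TLE3 (0.038) and ZNF341 (0.093). For the highest fraction against lysate, the pilot slope reversed for GSK3A (0.16), HNRPK (−0.0079), PSMC2 (plate 14, well H03; −0.10) and RBM38 (plate 14, well B10; 0.25), and that of GSK3A ran from −0.45 to 0.091 with 1 gradient left out. GSK3A in pilot protein output reversed over bin midpoints (−0.16) and ran from −0.074 to 0.32 with 1 sort left out. With library totals, EPHB1 reversed in pilot protein output (0.19), and EIF4B (−0.15), ENO1 (−0.14) and GSK3A (−0.029) in Tet-Off RNA, where doxycycline 0 h RNA gave −0.17 for ENO1 and −0.053 for GSK3A.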

Other observations

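Chosen after their results were seen were the 8 h and 20 h tests, the test for few molecules in fractions 1 and 2, the barcode tests, the test of plates as the whole cause and the 2 added gene lists; the genomic DNA test in fractions 1 and 2 and the test of plates as a part were set before. Of 207 ZNF, ZSCAN and ZKSCAN zinc-finger reporters 65 were higher in promoter protein output, 32 lower and 110 not called (median 0.90, camera adjusted p 0.00311, adjusted p = 0.296 with an estimated correlation). The list did not differ in pilot protein output, with 14 higher and 13 lower of 27 (camera adjusted p 0.991). In promoter RNA 71 were higher and 43 lower (camera adjusted p 0.0558). Of the promoter polysome slopes of these 207, 72 were higher and 20 lower (camera adjusted p 0.028, adjusted p = 0.108 with an estimated correlation). Without fractions 1 and 2, 88 were higher and 58 lower (camera adjusted p 0.157). The difference in mean promoter protein output between zinc-finger and other reporters was 0.92 (95% interval 0.61 to 1.24), and 0.70 (0.39 to 1.05) within library plates. This interval excludes 0, which argues against plates as the whole cause; because it reaches below 0.46, whether plates account for as much as 0.5 of the difference stays open. Of 25 HOX 3′UTRs 4 were higher and 10 lower (adjusted p 0.309). Plates held 4.83% of the variance of protein output and 9.71% of that of RNA. In the 16 genes with 2 reporters, protein output differed by a median of 1.86, against 2.47 in random pairs, and RNA by 1.10 against 0.83.

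After doxycycline, reporter shares moved away from those at 0 h until 3 to 4 h and then back, with r = 0.98 with 0 h at 20 h in both batches. In a mixture of 0 h, 4 h and DNA shares, which replaced a 2-part mixture after its DNA weight of 0 had been seen, the DNA weight at 20 h was at most 2.12% (0.50% to 6.64%), below the 10% set for genomic DNA as the cause. At 8 h the DNA weight was up to 8.83% (4.66% to 17.0%), which leaves genomic DNA open there. The 0 h shares had a weight of at least 76.9% at 20 h and 38.2% at 8 h. These weights restate how close the shares lie to those at 0 h, so whether reporter RNA was still made, or left, in 0 h proportions stays open. No biological explanation was tested.

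Fractions 1 and 2 stood apart from fractions 3 to 15, and the promoter slopes depend on them. Genomic DNA in them is argued against by r = −0.0968 between the ratio of fraction 1 to lysate and the ratio of DNA to RNA in PGK (0.0044 in CAG). In fractions 3 to 8 the same r was 0.41 to 0.62 in both promoters; a true tie between low RNA level and these fractions would give this too, so genomic DNA in those fractions stays open. For loss by chance from few molecules, r between PGK and CAG in fraction 1 was 0.696. Reporters of low share in both pools could lose reads in both and raise this r, so it does not exclude such loss. Barcodes of a reporter differed with an SD of 1.88 and 1.40 in fractions 1 and 2 of PGK. This SD was 0.63 and 0.38 in those of CAG, against 0.13 to 0.40 in fractions 3 to 15 of both. What these fractions hold stays open.

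Barcodes of a reporter differed in RNA per DNA in ways that recurred between cell pools. Their deviations correlated with r = 0.41 (0.36 to 0.46) between PGK and CAG, 0.52 (0.40 to 0.66) between PGK and Tet-Off and 0.62 (0.42 to 0.79) between CAG and Tet-Off, which argues against loss of cells by chance in each of these pools. With the pilot, r was 0.393 (0.19 to 0.57) for CAG and 0.41 (0.13 to 0.61) for Tet-Off; these intervals reach below the 0.3 set for it, so chance loss in the pilot pool stays open. Within reporters, protein output had a slope of 0.0117 on RNA in PGK (−0.22 to 0.23) and −0.060 in CAG, against 1.74 and 1.83 between reporters, with RNA of the other promoter as instrument so that noise in RNA does not flatten the slope. In the pilot, with Tet-Off RNA as instrument, it was 0.333 (−0.34 to 1.10) against 3.98. Each interval lies below 0.5 of the slope between reporters, which argues against a true difference in RNA level as the whole cause and is consistent with unequal reading of barcodes in the RNA libraries. A smaller true difference stays open, since RNA and protein output of barcodes correlated with r = 0.055 (0.0093 to 0.10) in PGK, 0.032 (−0.011 to 0.077) in CAG and 0.22 (−0.0006 to 0.39) in the pilot, and Tet-Off RNA with pilot protein output with 0.16 (−0.087 to 0.35). Causes that the pools share from before the reporters entered the separate lines were not tested.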
